A study of Arabidopsis thaliana with 77 samples.

How the data were processed

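Genomic DNA of rosette leaves was sequenced on a HiSeq2000 as pairs of 101-nt reads, per the labels. The authors deposited 1 file of single-base variant calls per library, in the variant call format (VCF 4.1, per the file headers). The submitters' processing notes name Bowtie, SAMtools, Bismark and the build TAIR10, without versions or roles, and the file headers give samtools 0.1.19-44428cd as the caller. Filters on the calls are not given in the sources used here. Each call has a quality score given by the authors' caller (phred-scaled, per the file headers), which ran from 3.01 to 222 in every deposited file. The total depth and the numbers of high-quality reads for the reference and alternative bases are also the authors' values. Mapping quality was 20 at every call, and no insertion or deletion was listed. The files list only called sites, so a site without a call may be a reference site or a site without coverage.

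Calls on chromosomes 1 to 5 were used as deposited in the main results. The chromosome lengths and the reference base of every such call matched the annotated reference assembly of TAIR10, from which gene models were taken. Mitochondrial calls could not be annotated, because the mitochondrial sequence used by the authors differs in length from that of the reference. Calls were compared between libraries by chromosome, position and called base. Between 11 and 18 calls per library listed more than 1 called base. These were compared as a whole and classed by the first base listed. Each change was translated on the longest coding sequence of a gene, and the 2 intron bases next to an exon counted as a splice site. Protein-altering means stop-gained, splice-site or missense. Pericentromeres were the regions within 3 Mb of approximate centromere positions at 15, 3.6, 14, 4 and 12 Mb of chromosomes 1 to 5. The library labelled rdr1 rdr2 rdr6 was heterozygous for a DDM1 change, so it is named by its label. The alignment names in the file headers share a prefix for it, 2-69 and 2-20, and differ for 3-72 and 3-75, and what the prefix stands for is not given.

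Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 4 lines. Computed p-values below 1e-300 were written as that bound. Recurrent genes and gene lists were set against 10000 seeded resamplings that drew each line's altered genes from 27444 protein-coding genes with probability proportional to coding length. Lists of 36 RNA silencing, 32 DNA methylation and chromatin, 30 centromere, kinetochore and cohesin, and 22 meiosis genes were fixed before the data were examined, as were the tests and most alternatives. The rule for named genes was also fixed then. It takes DDM1, RDR1, RDR2 and RDR6, list genes with a protein-altering call that is line-specific or shared by the 4 lines only, and up to 6 genes per line with a stop-gained or splice-site call, homozygous first and then by quality. It also takes up to 10 genes altered at different positions in 2 or more lines, and up to 10 altered in the 4 lines and not in the library labelled rdr1 rdr2 rdr6. Chosen after the data were seen were the class of calls with quality of 50 or more and at least 10 reads, the restriction to libraries with that shared prefix, and both zygosity contrasts. The contrast around DDM1 followed the whole-chromosome contrast, and all 8 tests were adjusted together.

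Alternatives were calls of at least the median quality of their library, calls with at least 10 reads, homozygous calls, calls outside clusters of 3 within 100 bp, sharing by position, other pericentromere widths of 2 and 5 Mb, a looser definition of line-specific, stop-gained and splice-site changes only, G/C to A/T changes only, mitochondrial calls, and leaving out each line. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and Biopython 1.88. The scripts were tested on simulated data. Translated effects matched an independent translation for 100% of 1999 random coding changes. For the substitution spectrum, a simulated excess of 40 percentage points came back as 39.1 to 41.3. For recurrent genes, random sets passed in 3.5% of 200 simulations over 27444 genes, and sets with 15 planted genes in 88.5%. The random sets were drawn with the same length weights as the resamplings. They check the computation and not whether those weights suit the real calls. Intervals on shares are Wilson 95% intervals and intervals on reads at a site are exact, and all cover counting error only.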

Results

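The data are single-base variant calls from the genomic DNA of 5 Arabidopsis thaliana libraries of the Columbia ecotype, made from rosette leaves of plants 4 weeks old. One library is labelled rdr1 rdr2 rdr6, a mutant combination that lacks RNA-dependent RNA polymerases of RNA silencing. The other 4 libraries come from episuppressor lines in a background labelled rdr1 rdr2 rdr6 ddm1, named 2-69, 2-20, 3-72 and 3-75, with 1 library per line. DDM1 is a chromatin remodelling ATPase that plants need to keep DNA methylation over transposons. Each line has 1 library of this kind here, so every value below describes a library, and tests over calls compare sets of calls within a library and not lines. Of the 77 samples of the series, these 5 are analysed here.

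The calls on chromosomes 1 to 5 numbered 6724 in the library labelled rdr1 rdr2 rdr6. They numbered 6992 in 2-69, 7329 in 2-20, 6939 in 3-72 and 6891 in 3-75, which gives 7038 ± 198 (SD, n = 4) over the lines. With 4 lines and 1 control library no exact permutation test could pass its threshold, so no difference in number was tested. Depth differed between libraries. The median depth at the calls was 35 reads in the library labelled rdr1 rdr2 rdr6, 37 in 2-69, 24 in 2-20, 17 in 3-72 and 23 in 3-75. At sites called in all 5 libraries the median depth ran from 24 in 3-72 to 56 in 2-69. Calls given as homozygous were 18.3% of the calls of the library labelled rdr1 rdr2 rdr6 (Wilson 95% interval 17.4 to 19.2). They were 25.3% in 2-69 (24.3 to 26.3), 18.0% in 2-20 (17.1 to 18.9), 22.4% in 3-72 (21.4 to 23.3) and 24.0% in 3-75 (23.0 to 25.1). These intervals, like those below, cover counting error only.

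The first question was whether the libraries carry the alleles their labels name. In DDM1 (AT5G66750, chromosome 5, 26648897 to 26653191, TAIR10 coordinates), the base change G26652152A (reference base, chromosome position, called base) was called in all 5 libraries. It lies in the coding sequence and changes the protein as C615Y (reference residue, residue number, changed residue). All 4 lines were homozygous, with 23 reads for the change in 2-69, 14 in 2-20, 10 in 3-72 and 7 in 3-75, and 0 reads for the reference base. The library labelled rdr1 rdr2 rdr6 was heterozygous at this site, with 9 of 19 reads for the change (47.4%, exact 95% interval 24.4 to 71.1). Its label names no ddm1 allele, so it is called the library labelled rdr1 rdr2 rdr6 throughout. In RDR6 (AT3G49500, chromosome 3, 18348974 to 18353673), the change G18352401A, which turns a codon into a stop (R269*), was homozygous in all 5 libraries. The reads for it numbered 23 in the library labelled rdr1 rdr2 rdr6, 37 in 2-69, 18 in 2-20, 11 in 3-72 and 29 in 3-75. No call fell inside RDR1 (AT1G14790, chromosome 1, 5093961 to 5098270) or RDR2 (AT4G11130, chromosome 4, 6780449 to 6784632). Insertion alleles do not appear as single-base calls, so these loci were not checked by the data.

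Calls were then compared between libraries, to separate calls made in all libraries from those made in a line alone. Each line carried many calls found in no other library. Of 15725 variants, keyed by chromosome, position and called base, 2883 (18.3%) were common to the 5 libraries and 7565 (48.1%) were line-specific, that is, called in 1 line and in no other library. Another 1057 were called in the library labelled rdr1 rdr2 rdr6 alone, and 128 (0.814%) were shared by the 4 lines and absent from it. In that library 36.0% of the common calls were homozygous, at a median depth of 51 reads. The common calls are therefore not all fixed differences from the reference. The line-specific calls numbered 1775 in 2-69, 1929 in 2-20, 2202 in 3-72 and 1659 in 3-75 (1891 ± 235, SD, n = 4). Their mean fell to 626.8 with quality of 50 or more and at least 10 reads. Their median quality was 63, 21, 25 and 18.1 in the same order of lines, and 552, 127, 430 and 463 of them were homozygous. When homozygous calls alone were compared between libraries, the mean was 432. That setting also counts as line-specific a homozygous call that was heterozygous in another library. The Jaccard index (shared calls over calls in either library) lay between 0.371 and 0.416 for the 6 pairs of lines, and between 0.404 and 0.471 for the 4 pairs with the library labelled rdr1 rdr2 rdr6. On the chromosome arms, calls shared by a pair of lines alone numbered 195 over the 6 pairs. Of these, 2 were G/C to A/T changes with quality of 50 or more and at least 10 reads in both lines, a quality class defined after the calls had been seen.

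G/C to A/T changes made up most line-specific calls and a minority of the common calls. Their share was 68.8% in 2-69 (Wilson 95% interval 66.6 to 70.9), 60.5% in 2-20 (58.3 to 62.7), 69.9% in 3-72 (68.0 to 71.8) and 55.6% in 3-75 (53.2 to 58.0). It was 18.4% (17.0 to 19.9) among common calls and 25.6% (23.1 to 28.4) among calls of the library labelled rdr1 rdr2 rdr6 alone, the background measured the same way. The excess over common calls was 50.4 percentage points in 2-69, 42.1 in 2-20, 51.5 in 3-72 and 37.2 in 3-75. It passed a two-sided Fisher's exact test in 4 of 4 lines, and the largest adjusted p over the lines was 8.05e-146 (Benjamini-Hochberg). Homozygous line-specific calls were G/C to A/T in 94.0% of cases in 2-69, 93.7% in 2-20, 94.2% in 3-72 and 93.1% in 3-75. Among heterozygous ones the shares were 57.4%, 58.2%, 64.1% and 41.1% in the same order. With quality of 50 or more and at least 10 reads, the G/C to A/T share of line-specific calls was 96.0% in 2-69, 96.2% in 2-20, 96.8% in 3-72 and 95.05% in 3-75. Such G/C to A/T calls numbered 929 in 2-69, 482 in 2-20, 575 in 3-72 and 422 in 3-75. Calls within a library are linked, so each p describes sets of calls.

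**Figure D1:**
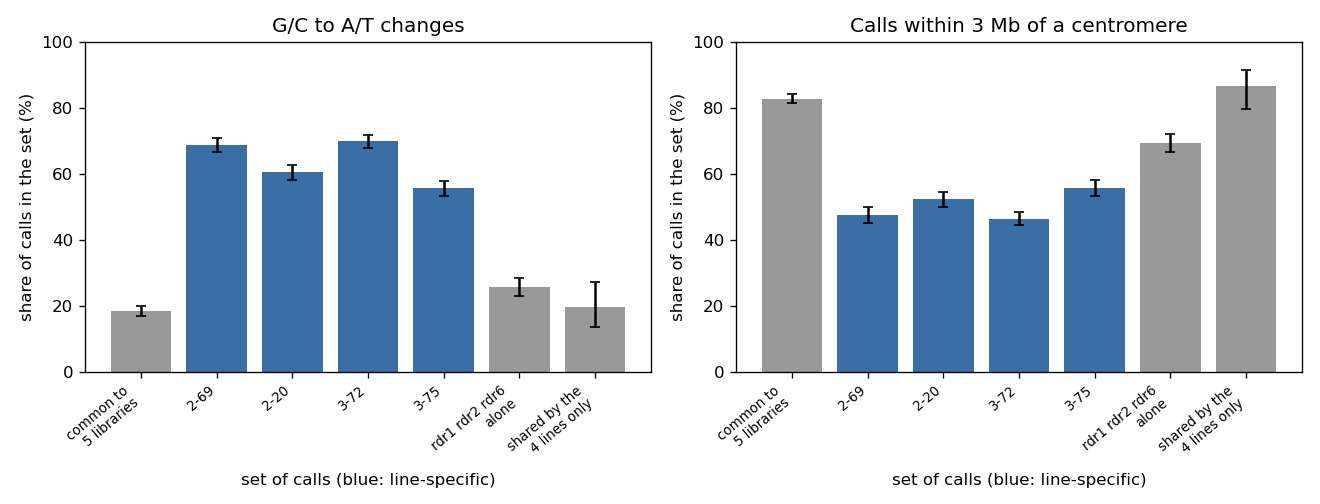
Share of G/C to A/T changes (left, percent) and of calls within 3 Mb of a centromere (right, percent) in each set of calls. Bars are shares, error bars are Wilson 95% intervals, blue bars are the line-specific calls of each line, and grey bars are the common calls, calls of the library labelled rdr1 rdr2 rdr6 alone and calls shared by the 4 lines only. Line-specific calls reach 55.6% to 69.9% on the left, against 18.4% for common calls.

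Line-specific calls lay on the chromosome arms more often than common calls did. Within 3 Mb of the centromere, a region that covers 25.2% of chromosomes 1 to 5, lay 82.9% of common calls (Wilson 95% interval 81.5 to 84.2). Of the line-specific calls, 47.5% lay there in 2-69 (45.2 to 49.9), 52.4% in 2-20 (50.1 to 54.6), 46.5% in 3-72 (44.4 to 48.6) and 55.7% in 3-75 (53.3 to 58.1). Calls of the library labelled rdr1 rdr2 rdr6 alone were pericentromeric in 69.4% of cases (66.6 to 72.1). The share was lower than among common calls in 4 of 4 lines, by two-sided Fisher's exact test with a largest adjusted p of 1.34e-85. The 500-kb window with most common calls began at position 11500001 of chromosome 5 and held 345 of them, against a median of 2 per window. Line-specific calls were also dense near centromeres, with 102 calls in 2-69, 102 in 2-20 and 100 in 3-72 in the window of chromosome 1 that begins at 15000001, against medians of 5, 5 and 7 per window. In 3-75 the fullest window was that of chromosome 5, with 60 calls. With quality of 50 or more and at least 10 reads, the density near centromeres was closer to that of the arms. Line-specific G/C to A/T calls of that class numbered 8.9 per Mb near centromeres and 7.43 on the arms in 2-69. The same densities were 4.83 and 3.78 in 2-20, 4.97 and 4.78 in 3-72, and 4.3 and 3.29 in 3-75.

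Each line carried between 209 and 362 protein-altering line-specific calls (275 ± 68.2, SD, n = 4). The mean fell to 169.5 with quality of 50 or more and at least 10 reads. It was 82.2 when homozygous calls alone were compared between libraries. Stop-gained changes numbered 13 in 2-69, 14 in 2-20, 13 in 3-72 and 9 in 3-75, and splice-site changes 4, 3, 3 and 4 in the same order. Missense changes numbered 277, 217, 346 and 196. The library labelled rdr1 rdr2 rdr6 alone carried 36 missense changes and 0 stop-gained or splice-site changes. In 3-75, homozygous stop codons fell in BSK1 (AT4G35230, chromosome 4, 16755092 to 16758358), a kinase of brassinosteroid signalling, as Q26*, and in SPPL2 (AT1G63690, chromosome 1, 23618012 to 23622396), a signal peptide peptidase-like protein, as W388*. The same line carried homozygous stops in AT5G52850, a pentatricopeptide repeat protein (Q774*), and in AT2G18220, a protein of the Noc2p family (R761*). It also carried homozygous splice-site changes in NAPRT1 (AT4G36940, G17418040A, donor of intron 6), a nicotinate phosphoribosyltransferase, and in AT1G64430 (G23936068A, acceptor of intron 10). In 2-69, homozygous stops fell in AT1G64500, a glutaredoxin family gene (Q133*), in the lectin protein kinase gene AT1G67520 (W221*), in AT2G27650 (W251*) and in BGLU24 (AT5G28510, Q104*), a beta glucosidase. A homozygous splice-site change fell in SVL2 (AT1G66970, C24993132T, donor of intron 7), and a heterozygous stop in AT1G17450 (W396*). In 3-72, AT3G17750, a protein kinase gene (Q780*), and HCAR (AT1G04620, W429*) carried homozygous stops. Heterozygous stops of that line fell in AT3G12440 (Q220*), SGT (AT3G07020, Q207*) and AT3G06160 (W127*), and a heterozygous splice-site change in PHYLLO (AT1G68890, G25898025A, acceptor of intron 4).

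In 2-20, none of the 17 stop-gained or splice-site calls was homozygous, against 5 of 17 in 2-69, 2 of 16 in 3-72 and 9 of 13 in 3-75. The calls of 2-20 with the best quality were stops in AT3G62870, a ribosomal protein gene of the L7Ae family (Q57*), AT1G11390 (W230*), AT2G23390 (Q79*) and GATA15 (AT3G06740, R117*), a GATA transcription factor. Splice-site changes fell in IP5PI (AT1G34120, G12428879A, acceptor of intron 7) and AT1G30860 (C10987504T, donor of intron 3). The missense-to-synonymous ratio was 2.66 in 2-69, 1.99 in 2-20, 2.26 in 3-72 and 2.39 in 3-75, against 3.06 among common calls. It was lower in 4 of 4 lines, and in no line did the two-sided Fisher's exact test pass after adjustment (adjusted p 0.495, 0.132, 0.242 and 0.344). All 4 contrasts share the same common calls, which held 51 synonymous changes. Against calls of the library labelled rdr1 rdr2 rdr6 alone the direction was the other way. Their ratio was 1.8, from 36 missense and 20 synonymous changes.

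Genes altered at different positions in several lines were counted, to see whether the lines share an altered gene. The gene altered in most lines with the best quality was AT2G29210 (chromosome 2, 12557979 to 12562367), annotated as a splicing factor with a PWI domain. It carried R179H in 2-20 (heterozygous, 9 of 14 reads), R204C in 3-72 (homozygous, 13 reads) and P404S in 3-75 (homozygous, 63 reads). In total 39 genes were altered in at least 2 lines, 36 of them in 2 lines and 3 in 3 lines, against 23.0 (95% range 15 to 32) in 10000 length-weighted resamplings (one-sided permutation p = 0.0009). With G/C to A/T changes only the count was 22 against 18.9 (permutation p = 0.253), and without 2-69 it was 15 against 11.02 (permutation p = 0.139). Genes altered in 2 lines included PAL1 (AT2G37040), a phenylalanine ammonia lyase of lignin and flavonoid synthesis, with D574N in 2-69 (homozygous) and P709L in 3-72 (heterozygous). Others were GRL (AT2G35110; V515M in 2-69 and D979N in 3-72), PCN (AT4G07410; E680K in 2-69 and P432L in 2-20), emb1379 (AT5G21140; R18Q in 2-69 and L159F in 2-20), AT1G03370 (A777V in 2-69 and L97F in 3-72), AT5G26850 (A878T in 2-20 and P476S in 3-75) and AT3G56840 (D398N in 2-69 and R315C in 3-72). AT2G08986 and AT5G28460 were altered in 3 lines each, but 2 of the 3 lines at AT5G28460 had calls with quality under 15 only. AT2G08986 lies at 3618058 to 3626460 of chromosome 2, where depth at its calls reached 2830 reads. Only 2 genes had a protein-altering call shared by the 4 lines and absent from the library labelled rdr1 rdr2 rdr6. They were AT2G08986 (K818R) and its neighbour AT2G07981 (H395Y), both pericentromeric. In 2-69 both calls were heterozygous, with 25 reads for K818R and 49 for the reference base, and 23 and 45 for H395Y. Their quality there was 22 and 56. Of all calls shared by the 4 lines only, 86.7% were pericentromeric and 8.59% were homozygous in 2-69.

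In the fixed gene lists, few members were altered and no count passed its test against resampling. Among 36 RNA silencing genes, 2 were altered, both heterozygous and in 3-72. They were DCL3 (AT3G43920, S516F), the Dicer-like enzyme that makes small RNAs for RNA-directed DNA methylation, and NRPE1 (AT2G40030, S848F), the largest subunit of RNA polymerase V. Resampling gave 3.50 genes (two-sided permutation p = 0.624, adjusted p = 1). Among 32 genes of DNA methylation and chromatin, 2 were altered: VIM3 (AT5G39550, A253V, homozygous in 3-72), which binds methylated DNA, and IBM1 (AT3G07610, D213N, heterozygous in 2-20), a histone demethylase. Resampling gave 2.28 (permutation p = 1, adjusted p = 1). Among 30 genes of centromere, kinetochore and cohesin, 4 were altered against 1.99 (permutation p = 0.271, adjusted p = 1). SMC5 (AT5G15920) carried L953F, homozygous in 3-75, and SMC6B (AT5G61460) carried P617S, homozygous in 2-20. SMC5 and SMC6B encode partners in a complex of chromosome maintenance and DNA repair. SMC6B lies within 5 Mb of DDM1 on chromosome 5. In 2-20, 21 of 23 line-specific G/C to A/T calls there were homozygous, so SMC6B shares its zygosity with most calls around it. SCC2 (AT5G15540, A886V), which loads cohesin, and CDC48A (AT3G09840, V223I) were heterozygous in 3-72. The calls in SCC2, CDC48A and IBM1 had quality of 43, 32 and 39, below the limit of the quality class defined above. With line-specific calls of that class, 2 genes of centromere, kinetochore and cohesin were altered, against 1.27 by resampling. For DNA methylation and chromatin it was 1 gene against 1.46, and neither count passed. Among 22 meiosis genes, MUS81 (AT4G30870, P54L) and FANCM (AT1G35530, T214I) were altered, both homozygous in 2-69, against 1.46 by resampling (permutation p = 0.878, adjusted p = 1).

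Zygosity along the chromosomes was compared only after the calls had been seen. Line-specific G/C to A/T calls fell in long homozygous and heterozygous stretches that differed between lines. In 2-20, chromosome 5 was homozygous in 94 of 97 such calls with quality of 50 or more and at least 10 reads, and chromosomes 1 to 4 in 5 of 385, but over calls of any quality the shares were 58.4% and 1.52%. In the other lines homozygous calls lay on every chromosome, and on chromosomes 1 to 4 they made up 51.9% in 2-69, 41.3% in 3-72 and 74.6% in 3-75 with those limits, and 40.6%, 20.7% and 46.1% over calls of any quality. Within 5 Mb of DDM1, over line-specific G/C to A/T calls of any quality, 35 of 35 were homozygous in 2-69, 21 of 23 in 2-20 (91.3%), 42 of 48 in 3-72 (87.5%) and 22 of 26 in 3-75 (84.6%). With quality of 50 or more and at least 10 reads, which heterozygous calls pass less often, the counts were 35 of 35, 18 of 18, 33 of 34 and 18 of 18. Over all line-specific G/C to A/T calls, a contrast of the whole of chromosome 5 with chromosomes 1 to 4 was tried first. Calls in 1 stretch share their zygosity, and the tests of this and the next contrast count them as independent. Their p-values therefore overstate the evidence. The homozygous share was higher on chromosome 5 by 56.9 percentage points in 2-20 (Fisher's exact test, adjusted p = 2.55e-81), 25.5 in 3-72 (3.99e-19) and 7.0 in 2-69 (0.0363), and in 3-75 the difference of 2.45 did not pass (0.532). In 2-69 it no longer passed with calls of at least the median quality (adjusted p = 0.141, Fisher's exact test), with quality of 50 or more and at least 10 reads (0.0755), with zygosity by read share (0.0577) or without 2-20 (0.0561). A second contrast, of calls within 5 Mb of DDM1 with chromosomes 1 to 4, was chosen after that result. It gave 59.4 percentage points in 2-69, 89.8 in 2-20, 66.8 in 3-72 and 38.5 in 3-75, with a largest adjusted p of 0.000122 by Fisher's exact test, adjusted over the 8 tests of both contrasts.

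**Figure D2:**
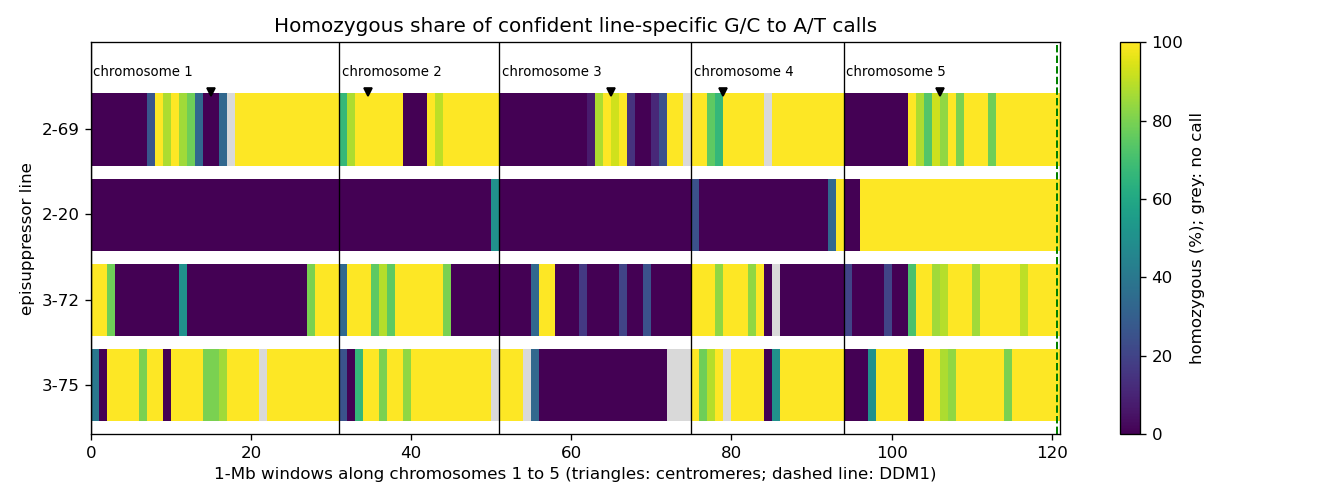
Homozygous share (colour, percent) of line-specific G/C to A/T calls with quality of 50 or more and at least 10 reads, in 1-Mb windows along chromosomes 1 to 5 (horizontal axis) for each episuppressor line (rows). Grey windows hold no such call, triangles mark centromeres and the dashed line marks DDM1, around which 18 of 18 calls of 2-20 and 33 of 34 of 3-72 were homozygous.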

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

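Apart from the cytosine context, the tests of explanations in this part were chosen only after the result was seen. Of 57 measures compared over the 4 lines, 5 had a line far from the other 3. Chance flags about 1 in 20 independent measures, but these largely recount the same calls, so the number flagged cannot be judged against that rate. The median quality of the calls was highest in 2-69, at 58 for all its calls and 63 for its line-specific calls. Line 2-69 also had the highest density of confident line-specific G/C to A/T calls near centromeres, 8.9 per Mb. It was highest on the arms too, at 7.43 per Mb against 3.78 in 2-20, 4.78 in 3-72 and 3.29 in 3-75. The confident class depends on depth, which was greatest in 2-69 (median 37 reads against 24, 17 and 23). Over calls of any quality, line-specific G/C to A/T calls numbered 1221 in 2-69, 1167 in 2-20, 1540 in 3-72 and 923 in 3-75. Line 2-20 had the fewest homozygous protein-altering line-specific calls, 18 against 109, 98 and 99 in 2-69, 3-72 and 3-75. Among confident G/C to A/T calls (quality of 50 or more and at least 10 reads) within 5 Mb of DDM1, the homozygous share was 97.1% in 3-72 and 100% in the other lines, a gap of 1 call of 34. With the other 3 lines tied at 100%, any lower value would have been flagged. Over calls of any quality it was lowest in 3-75, at 84.6%.

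The excess of G/C to A/T changes among line-specific calls was weighed against 3 causes. Mis-mapped reads from repeats would lose it on the arms, where the smallest excess over common calls was still 47.2 percentage points. Damage of DNA during library preparation would favour heterozygous calls. Instead, the G/C to A/T share was higher among homozygous than among heterozygous calls, by at least 30.1 percentage points in each line. This speaks only to the homozygous calls, which were 6.58% to 31.1% of the line-specific calls. Among heterozygous ones 41.1% to 64.1% were G/C to A/T, and the test cannot tell whether damage added to those. Deamination of methylated cytosines may contribute and stays open, since 18.3% of the changed cytosines on the arms were in CG, against 13.0% of all cytosines there, which is below the 50% set for it as the cause and just outside the 5 points set against it. Treatment with an alkylating mutagen, which the labels do not name, was not tested.

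The heterozygous call at C615Y in the library labelled rdr1 rdr2 rdr6 was weighed against a mixture with a line and against a paralog. DNA of a line mixed in would bring that line's homozygous changes along, but at most 0.601% of a line's own homozygous G/C to A/T calls on the arms were also called in that library. Reads from a paralog would show reference bases in the lines too, and 0 reads among their 54 reads did. A plant heterozygous for the DDM1 change is a candidate explanation, with 47.4% of 19 reads for it. A pool of plants of different DDM1 genotypes would give the same share and stays open.

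Homozygous line-specific calls around DDM1 on chromosome 5 in all 4 lines may reflect linkage to the DDM1 locus. The lowest homozygous share within 5 Mb of it was 97.1% among confident calls and 84.6% over calls of any quality. This share restates the pattern and does not single out DDM1. In the 1-Mb window of chromosome 5 that begins at 13000001, confident G/C to A/T calls were homozygous in 12 of 12 cases in 2-69. The counts were 7 of 7 in 2-20, 8 of 8 in 3-72 and 5 of 6 in 3-75. In the first 5 Mb of that chromosome the shares over calls of any quality were 0% in 2-69, 40% in 2-20, 2.99% in 3-72 and 16.3% in 3-75, and among confident calls 0%, 76.9% (10 of 13), 5% and 17.4%, so the contrast is weakest in 2-20. Coincidence of homozygous blocks is argued against by random circular shifts of the 1-Mb windows, since 15 windows were homozygous in all 4 lines against 4.02 by chance among confident calls (permutation p = 0.0029), and 6 against 0.469 over calls of any quality (permutation p = 0.0011), all between 11 and 27 Mb of chromosome 5, the only chromosome where 2-20 had more than a few homozygous calls. For heterozygous sites called homozygous at low depth, the share with 15 or more reads was 76.9% (10 of 13) in 3-72, short of the 80% set against it, but low depth as the cause of the contrast with chromosomes 1 to 4 is argued against by a test added after that, in which such calls kept a difference of at least 59.4 percentage points in each line. Linkage to a selected change other than DDM1 on the same chromosome was not tested.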

How the results depend on the processing

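The class of confident calls, the restriction to libraries with a shared header prefix and both zygosity contrasts were chosen after the data were seen. Of 335 values recomputed under 18 settings, 305 kept their direction and their side of the threshold or stayed within 1.5 times. Not every result can be recomputed under every setting. The G/C to A/T excess kept both under the 13 settings run for it (26.2 to 78.4 percentage points), as did the pericentromeric deficit under 14 (-55.3 to -18.7), the missense-to-synonymous contrast, which never passed, under 12 (odds ratio 0.331 to 0.965, lowest adjusted p 0.0517), and the contrast around DDM1 under 11 (25.4 to 98.7). No paired analysis was possible because the labels give the 5 libraries used no replicate numbers, and 1 library stands against the 4 lines.

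With calls of at least the median quality, the mean number of calls was 3547 and that of the library labelled rdr1 rdr2 rdr6 3413, with 1666 common and 957.5 line-specific calls. With homozygous calls only these were 1573, 1231, 918 and 432, with 82.2 protein-altering calls. With confident line-specific calls there were 626.8 line-specific and 169.5 protein-altering calls. Fewer calls enter each of these settings by construction. Except for the confident class, limits on quality, depth, zygosity or clusters were applied before the libraries were compared. A line-specific call under such a limit may therefore have been called in another library, outside the limit.

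The count of genes altered in several lines stayed above expectation but no longer passed with G/C to A/T only (22 against 18.9) and with confident calls (13 against 9.20). It fell below it with homozygous calls only (2 against 2.11) and with stop-gained and splice-site only (0 against 0.0842). Leaving out a line gave 15 to 28 genes, and 15 without 2-69 no longer passed. The cause was not tested.

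No list passed under any setting, but counts crossed their expectation. DNA methylation and chromatin had 2 genes with median quality and 1 with homozygous calls, and 1 to 2 when a line was left out. Centromere, kinetochore and cohesin had 0 with stop-gained and splice-site only and 1 with the shared header prefix. Meiosis had 0 with stop-gained and splice-site only, and 0 to 2 when a line was left out.

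On the whole of chromosome 5 the difference in 2-69 no longer passed with median quality (5.65 percentage points), confident calls (6.82), zygosity by read share (6.42) or without 2-20 (6.30, and 6.30 to 7.51 over the lines left out). In 3-75 it turned to -1.32 with median quality and -1.89 with confident calls. The cause was not tested. Depth limits 3-72 most, with a median of 17 reads per call. Mitochondrial calls could not enter the position or protein results.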

Other observations

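The test of AT2G29210 was chosen after its values were seen. AT2G29210, the splicing factor gene altered in 3 lines, was the only gene that confident calls altered in 3 or more lines. Chance placement of altered genes is not excluded, since length-weighted resamplings gave such a gene with permutation p = 0.0819. Its coding sequence of 2637 nt is longer than that of 93.6% of genes. A role of AT2G29210 in the suppressor lines may be worth a test in further lines.

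Mitochondrial calls numbered 144 in the library labelled rdr1 rdr2 rdr6 and 149, 148, 141 and 147 in 2-69, 2-20, 3-72 and 3-75. Calls found in no other library numbered 1 in the library labelled rdr1 rdr2 rdr6 and 3, 2, 2 and 5 in the lines. With 1 library per line and so few such calls, whether a line differs from that library cannot be told. Confident heterozygous G/C to A/T calls on the arms had a mean alternative read share of 52.4% in 2-69, 56.4% in 2-20, 61.7% in 3-72 and 55.9% in 3-75. At low depth the quality limit may keep calls with more reads for the change. The median depth was 37, 24, 17 and 23 reads in the same order. A difference between lines cannot be told from these shares.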
